A study of Mus musculus with 6 samples.

How the data were processed

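RNA was measured in CCR6+ group 3 innate lymphoid cells (ILC3) sorted from the ileum of mixed bone marrow chimeras, mice whose blood system was rebuilt from a mixture of 2 donors. Per the labels' protocols, 6-week-old recipients received 1000 rad before transfer of wild-type CD45.1 marrow together with Vipr2-deficient CD45.2 or CD45.1/2 marrow. An antibody against Thy1.2 (200 µg a day over 4 days) then depleted the remaining intestinal ILC3, and cells were taken 6 to 7 weeks after the last dose. The distal 14 cm of small intestine was digested enzymatically. Live lymphocytes negative for T, B, NK and myeloid lineage markers and positive for Thy1.2 and CCR6 were sorted by CD45 allotype. Libraries were prepared with SMART-Seq HT, a low-input full-length cDNA kit, and sequenced on a NextSeq 500.

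The submitters' processing notes name STAR 2.6.1d, featureCounts, Subread 1.6.2, DESeq2 and the mouse genome build GRCm38, without their roles. The gene annotation and strand setting are not given in the sources used here. SMART-Seq cDNA does not mark strand, so reads of overlapping and antisense genes cannot be told apart. The deposited table holds 1 normalized signal value per gene and library for 45808 genes. Its values behave as gene counts divided by 1 size factor per library. In each of the 6 libraries 100% of the values were whole multiples of the smallest value above 0, within a tolerance of 1e-06, so whole reads were recovered by division. The recovered totals were 34617430, 33088499 and 31395314 reads in wild-type libraries 3, 4 and 5, and 33901577, 32089662 and 31480074 in knockout libraries 3, 4 and 5. A gene with no reads in a library could make up at most 0.0867 to 0.0956 ppm of the reads, the limit that a count of 0 allows at 3 reads. Exact (Clopper-Pearson) 95% intervals and these limits cover counting error only, since PCR copies are not independent molecules. Spreadsheet software had turned 27 gene names into dates, of which 18 passed the filter, and 8 rows shared a name with another. These rows were tested but not named.

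Groups were taken from the names of the table's columns, which give genotype and a number from 3 to 5. The sample labels conflict: for 2 of the 6 samples the title names the other genotype than the description, the genotype field and the CD45 gate do. No column was therefore tied to 1 mouse, and library numbers below are column numbers. This grouping was chosen before any gene's values were examined. The design had planned to group by description, with the titles as an alternative. The column names give the same grouping as the titles, and the grouping by description was run as an added alternative. The series' design text says that cells of both genotypes came from the same mice, but the column numbers could not be linked to mouse numbers, so the unpaired comparison was used. Libraries of 1 group were taken as separate samples. No 2 of them agreed within counting noise, since chi-square per degree of freedom was 29.17 or more in every pair.

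The comparison of knockout with wild type used limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(normalized value + 1). The 14364 genes with a mean of at least 10 over the 6 libraries were tested two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Error terms are SDs over the 3 libraries of a group for levels and standard errors (SE) for log2 fold changes. Before the data were examined, 28 gene lists, the test designs, the rule for named genes and most alternatives were fixed. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists with at least 3 tested members. Estimated correlations and fry were alternatives. Members were also adjusted over the list alone. Genes within 20 Mb of Ptprc, which encodes CD45, and of Vipr2 were tested the same way. Positions came from the GENCODE M21 annotation of GRCm38, which placed 94.6% of the tested genes by symbol. It can differ from the authors' annotation.

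The genes named in the text followed 1 rule. Vipr2 came first. In each direction 10 genes were taken, first those past the threshold whose groups did not overlap, by size, then those with the smallest unadjusted p, stated to have missed the test. The rule had asked for the same direction in all pairs of 1 mouse, which could not be formed. Il22, Il17a, Il17f, Csf2, Ccr6, Rorc, Il23r, Il7r and Vipr1 were named whatever their test. From each list up to 4 members past the threshold over all genes and up to 4 past it over the list alone were named, or otherwise up to 2 with the smallest p. The 3 most abundant members of lists for other cell types were given as levels.

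Alternatives changed 1 choice at a time, except that the block was also combined with edgeR and DESeq2 and a block by described mouse with the described genotype, and that edgeR and DESeq2 used their own filters (14144 and 17122 genes tested without the block): a block for the column number, other pseudocounts, filters, scalings and weights, each library or column number left out, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. The limma and edgeR tests were run on simulated counts for the real genes, with 200 changed genes. Camera at the preset correlation was run on a separate simulation of shifted and unchanged lists. The other alternatives, DESeq2, fry and estimated correlations among them, were not simulated. With 14233 genes tested in the simulated comparison of knockout and wild type, limma recovered 42.9% of the genes changed by 1 on the log2 scale, 75.0% of those changed by 2 and 89.4% of those changed by 4. Among simulated genes with a mean of at least 1000 it recovered 81.5% at a log2 change of 1. The Benjamini-Hochberg cutoff grows laxer as more genes change. The simulation held 200 changed genes and the real comparison called 4, so these shares can overstate recovery in the real data.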

Results

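Gene expression was compared between Vipr2-deficient and wild-type CCR6+ ILC3 that had developed side by side in the ileum of chimeric mice. ILC3 are tissue lymphocytes that secrete IL-22 and IL-17. VIPR2 is a Gs-coupled receptor for vasoactive intestinal peptide (VIP), a neuropeptide of gut neurons. The series asks how this receptor acts on ILC3. There were 3 libraries per genotype, with 31395314 to 34617430 reads assigned to genes in each. Il22 had the highest mean level and took 1.59% (95% interval 1.585 to 1.594) to 2.05% (2.041 to 2.051) of the reads. In knockout library 4 Junb had more reads than Il22 (529352 against 510119).

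Vipr2 RNA was almost absent from the libraries named knockout. The wild-type libraries held 4696, 4025 and 7592 Vipr2 reads and the knockout libraries 23, 10 and 21. The normalized read count was 5408 ± 2210 (SD, n = 3) in wild type and 18.0 ± 6.89 (n = 3) in knockout, a level of 0.332% of wild type. The log2 fold change was −8.16 ± 0.39 (SE; limma adjusted p = 0.00068). Vipr2 lies on chromosome 12 at 116077726 to 116146261 (GRCm38, plus strand) and shares part of its span with Gm20658. The genotype in the column names matched Vipr2 in all 6 libraries. For 2 samples the description names the other genotype than the title, so the descriptions, followed through the titles, would move 1 library rich in Vipr2 and 1 nearly without it to the other group. Vipr1, the other VIP receptor of this family, was listed at 0 in 5 libraries and at 11.5 in wild-type library 5.

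Besides Vipr2, 3 genes changed. Ctse, which encodes the aspartic protease cathepsin E, fell from 6244 ± 935 (SD, n = 3) normalized read counts in wild type to 412.2 ± 143 (n = 3) in knockout. Ptgs2, which encodes the prostaglandin-producing enzyme COX-2, rose from 5420 ± 373 to 17100 ± 1700, a 3.15-fold rise. Btg2, an antiproliferative immediate early gene, rose from 13890 ± 1800 to 39810 ± 3190, a 2.87-fold rise. The log2 fold changes were −3.96 ± 0.24 (SE) for Ctse, 1.65 ± 0.097 for Ptgs2 and 1.52 ± 0.11 for Btg2, with limma adjusted p = 0.0013, 0.0013 and 0.0030. All 3 genes lie on chromosome 1: Ctse at 131638306 to 131675505, Btg2 at 134075170 to 134079120 and Ptgs2 at 150100031 to 150108227. These positions are 6.42, 3.99 and 12.0 Mb from Ptprc, the gene of the CD45 allotype by which the 2 genotypes were sorted. No annotated gene overlaps any of the 3.

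**Figure D1:**
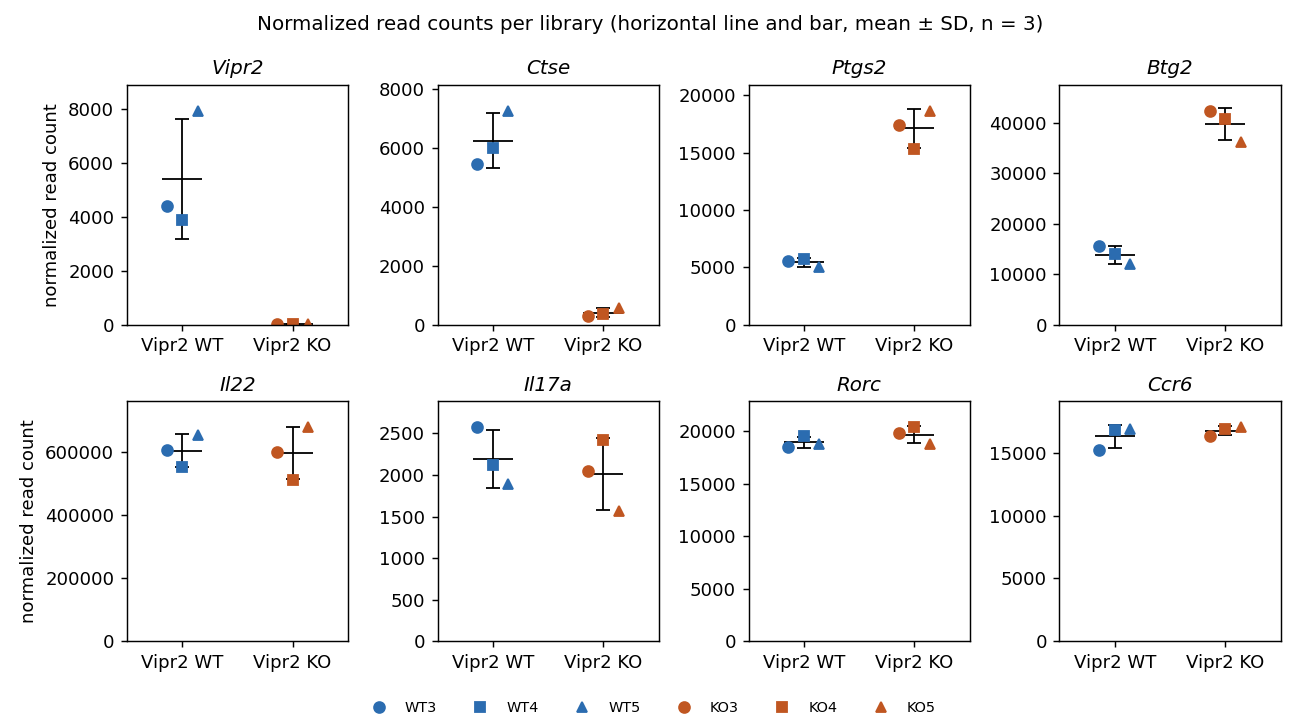
Normalized read counts (vertical axes, linear from 0) of 8 genes in wild-type (blue) and knockout (orange) libraries. Symbols mark the column number, and horizontal lines with bars give the mean and SD of 3 libraries. Vipr2 and Ctse were lower and Ptgs2 and Btg2 higher in every knockout library, while the genotypes overlapped in Il22, Il17a, Rorc and Ccr6.

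In all, 4 of 14364 genes passed the threshold in limma, 2 up and 2 down, and 742 (5.17%) had an unadjusted p under 0.05. The same 4 genes were called by edgeR's quasi-likelihood test on the recovered reads. DESeq2 called 65 genes, 37 up and 28 down, of which 7 lay within 20 Mb of Ptprc and 20 had no reads in any library of 1 genotype. Without knockout library 4 the Btg2 adjusted p was 0.052. With both libraries numbered 3 left out no gene was called, and without both numbered 4 only Vipr2 was.

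The remaining genes that the naming rule selected missed the test in limma. Among those higher in knockout were Wdfy1 (log2 fold change 1.00 ± 0.14 SE, adjusted p = 0.256), Zfp703 (0.61 ± 0.11), the aminopeptidase gene Rnpep (1.02 ± 0.17), Gm26642 (1.14 ± 0.21) and Thsd7b (1.61 ± 0.29). Rnpep (135262712 to 135284084) and Gm26642 (135248561 to 135266443) overlap in part on chromosome 1, so reads from the shared stretch cannot be separated. Spp1, which encodes osteopontin, was listed at 0 in the wild-type libraries and at 50.1 ± 6.77 (SD, n = 3) in knockout. Avpr1a and Zfp941 were also at 0 in wild type, against means of 49.4 and 53.3. Lower in knockout were the chemokine receptor gene Cxcr4 (−0.78 ± 0.099, adjusted p = 0.169) and Akap12, a scaffold of cAMP-dependent kinase (−1.28 ± 0.23, adjusted p = 0.529). Fads1, Cmah, Evx1 and Zfp612 were listed at 0 in the knockout libraries, with wild-type means of 160.9, 52.1, 71.6 and 42.5. The immunoglobulin segments Ighv1-53 and Iglc3, which share sequence with related segments, had wild-type means of 2671 and 89.7 and knockout means of 0 and 0.948.

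The cytokine genes of ILC3 did not pass the unpaired tests. Il22 stood at 604100 ± 51500 (SD, n = 3) normalized read counts in wild type and 596800 ± 83400 (n = 3) in knockout, and the 95% interval of its log2 fold change ran from −0.27 to 0.22. Il17a was at 2196 ± 348 and 2012 ± 431 (interval −0.57 to 0.30). Il17f was at 44870 ± 11000 and 41540 ± 10900 (−0.68 to 0.45), and Csf2, the gene of GM-CSF, at 11300 ± 2630 and 10770 ± 3080 (−0.60 to 0.44). In wild-type and knockout library 5 Il17f was at 0.628 and 0.607 of the others of their genotype, which widens its unpaired interval. At every column number Il17f was lower in knockout: 48337.4, 47280.9 and 29000.1 in libraries 3, 4 and 5 against 52267.4, 50176.6 and 32177.4 in wild type. By number Il22, Il17a and Csf2 went both ways, and no label ties a number to a mouse. None of the 16 ILC3 cytokine genes passed the test over all genes or adjusted over the list alone, with 8 higher and 8 lower (camera adjusted p = 0.888). Lta had the smallest p, with a log2 fold change of 0.21, and Il10 followed at −1.92 from means of 21.7 and 8.92. Il10 lies within 20 Mb of Ptprc, a stretch that the design ties to genotype. With the column number as a replicate block camera again did not call the list (adjusted p = 0.93), but fry in either direction did (adjusted p = 0.0087).

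Genes of ILC3 identity and cytokine sensing were likewise close. The log2 fold change was 0.04 (95% interval −0.12 to 0.20) for Ccr6, 0.05 (−0.09 to 0.20) for Rorc, which encodes the lineage factor RORγt, 0.01 (−0.29 to 0.30) for the IL-23 receptor gene Il23r and −0.05 (−0.19 to 0.08) for Il7r. Of 26 identity genes none passed, 17 being higher and 9 lower (camera adjusted p = 0.644). The smallest p belonged to the lymph node homing receptor gene Ccr7 (0.42 ± 0.17 SE) and to Cd83 (−0.14 ± 0.060). Of 16 cytokine receptor genes none passed, 10 being higher (adjusted p = 0.197), with Il6st at 0.61 and Il4ra at 0.12. In the migration and adhesion list (22 tested, camera adjusted p = 0.463) Cxcr4 was the 1 member that fell adjusted over the list alone (limma adjusted p = 0.00129). Cxcr4 lies within 20 Mb of Ptprc, a stretch that the design ties to genotype.

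Genes downstream of cAMP, the messenger that Gs-coupled receptors raise, were as a list slightly higher in knockout. Of 24 genes of the cAMP and CREB response, 16 were higher and 8 lower, with a median log2 fold change of 0.13 (camera adjusted p = 0.0307, but adjusted p = 0.366 with an estimated correlation). The list's mean was −0.005, and its sparse member Ppargc1a was at −2.21. No member passed over all genes or over the list alone. The clock gene Per1 (0.35 ± 0.078 SE, limma adjusted p = 0.0526 over the list alone) and the nuclear receptor gene Nr4a2 (0.21 ± 0.064) had the smallest p. Without wild-type library 3 the list's adjusted p was 0.148, without wild-type library 4 it was 0.067, and without knockout library 5 it was 0.172. Leaving out any other 1 library gave 0.0112 to 0.0245. Without both libraries numbered 3, 4 or 5 it was 0.118, 0.0522 and 0.00641. With the column number as a replicate block the camera adjusted p was 0.000143, but 0.426 with an estimated correlation. At every number 11 of 24 genes were higher in knockout and 4 lower. Fos, Fosb, Dusp1 and Atf3 are also members of the immediate early list, and without these 4 genes 12 of 20 were higher (camera adjusted p = 0.0447). Only genes named in both lists were taken out, so this does not separate a cAMP response from an immediate early response. In the libraries numbered 5 of wild type and knockout Fos was 1.85-fold and 1.74-fold and Atf3 2.11-fold and 1.77-fold higher than in the others of their genotype. The 19 cAMP pathway components did not pass as a list (11 higher, 8 lower, camera adjusted p = 0.909). Their smallest p belonged to Prkacb (−0.29) and Adcy9 (−2.86, means of 17.7 and 3.16). The list of Vipr2 and other Gs-coupled or neuropeptide receptors was lower (10 tested, camera adjusted p = 0.0459, 0.366 with an estimated correlation), and without Vipr2 its adjusted p was 0.52. It was 0.0974 to 0.221 when any 1 library other than knockout library 5 was left out, 0.0531 with TMM scaling and 0.0892 with edgeR.

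Immediate early and dissociation genes, which cells induce within minutes of stimulation or handling, were also higher in knockout as a list. Of 26 members 23 were higher, with a median log2 fold change of 0.10 (camera adjusted p = 0.0307, 0.667 with an estimated correlation). Btg2 was the only member that rose, over all genes and adjusted over the list alone. Without genes within 20 Mb of Ptprc, among them its members Btg2 and Ier5, the list's adjusted p was 0.101. The median log2 fold change was 0.096 before (quartiles 0.065 and 0.147) and 0.096 after (0.065 and 0.14, 21 of 24 genes above 0), and the mean was 0.181 and 0.13. The list's adjusted p was 0.341 without wild-type library 3, 0.417 without wild-type library 4, and 0.867 with the opposite sign without knockout library 5, but 7.61e-07 without both libraries numbered 5. With the column number as a replicate block the camera adjusted p was 1.5e-11, but 0.426 with an estimated correlation. The libraries numbered 5 of both genotypes stood above the others in these genes: Dnajb1 was 3.37-fold and 3.44-fold and Fos 1.85-fold and 1.74-fold higher in wild-type and knockout library 5.

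Mitochondrially encoded transcripts were lower in knockout in all 11 tested members, with a median log2 fold change of −0.21 (camera adjusted p = 0.00146, 0.366 with an estimated correlation). Without both libraries numbered 3 the adjusted p was 0.104. They made up 0.242% to 0.267% of the reads in wild type and 0.200% to 0.235% in knockout. Only mt-Cytb fell adjusted over the list alone (−0.35 ± 0.085 SE, limma adjusted p = 0.0409). Cytosolic ribosomal protein genes were lower in 40 of 52 (median −0.05, camera adjusted p = 0.0384, 0.584 with an estimated correlation), led by Rpl34 (−0.21) and Rpl4 (−0.08). With TMM scaling their adjusted p was 0.0531. Without wild-type library 5 it was 0.443, without wild-type library 4 0.0614, and without knockout libraries 4 and 5 in turn 0.148 and 0.215. Nuclear genes of oxidative phosphorylation (29 of 40 lower, adjusted p = 0.0577) missed the threshold, with Cox6c at −0.18 and Ndufv2 at −0.19.

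Other programmes did not pass as lists in the unpaired test, and none of their members passed over all genes or adjusted over the list alone. For the NF-κB response (15 of 20 higher, camera adjusted p = 0.0823) Nfkbid was at 0.27 and Birc3 at −0.23. For the STAT3 and IL-23 response (14 of 20 higher, adjusted p = 0.0577) Fosl2 was at 0.19 and Pim1 at 0.27. Of 25 interferon response genes 16 were higher (adjusted p = 0.172), with Ifit1 at 1.04 ± 0.34 SE and Gbp7 at 0.24. Glycolysis genes (14 of 20 higher, adjusted p = 0.197) included Hk2 at 0.21 and Pkm at 0.14. Cholesterol synthesis (9 of 22 higher, adjusted p = 0.776) included Insig1 at 0.40 and Hmgcr at 0.22. MHC class II genes (10 of 13 higher, adjusted p = 0.536) included H2-Ab1 at 0.13 and Ctss at 0.10. Proliferation genes were split (16 higher and 14 lower of 30, adjusted p = 0.922). The sparse transcripts Cenpf (means of 1.74 in wild type and 29.7 in knockout) and Aurkb (59.4 and 11.1) had their smallest p. With the column number as a replicate block camera called the NF-κB list (adjusted p = 0.0123) and the STAT3 and IL-23 list (adjusted p = 0.022). With an estimated correlation under the block both were at 0.426.

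**Figure D2:**
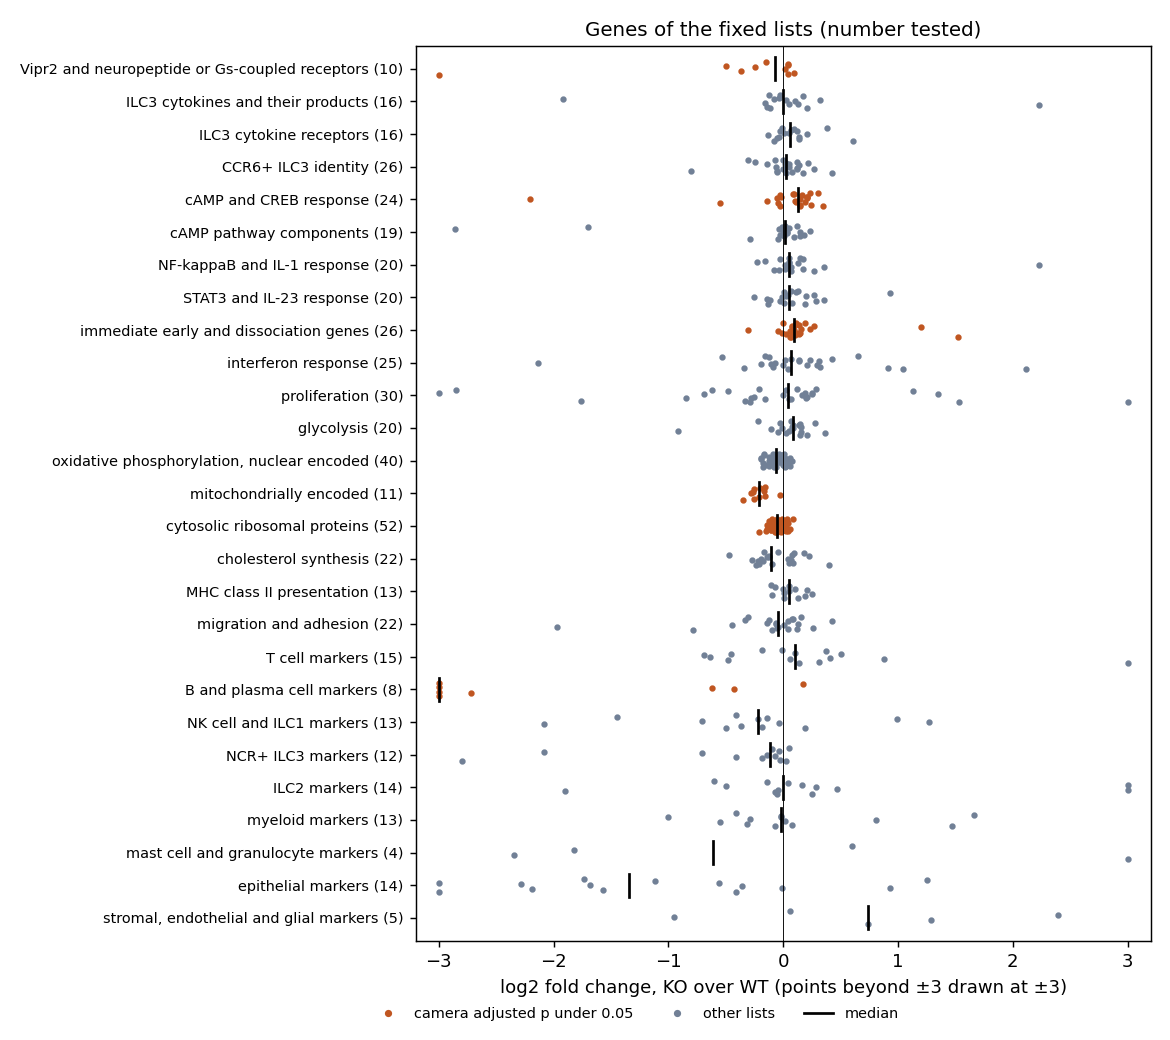
Log2 fold change, knockout over wild type (horizontal axis), of each tested gene (points) in 27 fixed lists, with the list's median (black bar). Orange marks the 6 lists with a camera adjusted p under 0.05 at the preset correlation. Most medians lie near 0, and that of the B and plasma cell list, −3.60, lies beyond the drawn range.

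Among markers of other cell types, those of antibody-secreting plasma cells stood apart. The list of B and plasma cell markers was lower in knockout in 7 of 8 tested genes (camera adjusted p = 0.000187, adjusted p = 0.366 with an estimated correlation, 0.0676 on DESeq2 statistics and 0.0738 without both libraries numbered 5). Igha, the IgA heavy chain gene, was at 133295.7, 27040.5 and 175639.6 normalized read counts in wild-type libraries 3, 4 and 5. In knockout libraries 3, 4 and 5 it was at 31670.4, 31.1 and 34.7. Igkc had means of 66980 in wild type and 5488 in knockout, Jchain 23100 and 1201, and Mzb1 158.6 and 11.7. These 4 genes fell adjusted over the list alone (limma adjusted p = 0.0322 for Igha, Igkc and Jchain and adjusted p = 0.0435 for Mzb1). Over all genes they missed the test (limma adjusted p = 0.96 for each). The exact two-sided permutation p for Igha was 0.2, where 3 against 3 libraries cannot go below 0.1. Jchain and genes with immunoglobulin-type names made up 0.196% to 1.15% of the reads in wild type and 0.196% in knockout library 3. In knockout libraries 4 and 5 the share was 0.00253% and 0.00231%. Names were matched by their first letters, which also takes in Ighmbp2, not an immunoglobulin gene. Ighm did not follow Igha, at 304.8 and 272.7 normalized read counts in knockout libraries 4 and 5 against 134.6 in knockout library 3. The gate excluded CD19-positive cells and required Thy1.2 and CCR6. The B cell genes Cd19, Ms4a1 and Pax5 were listed at 0 in every library.

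**Figure D3:**
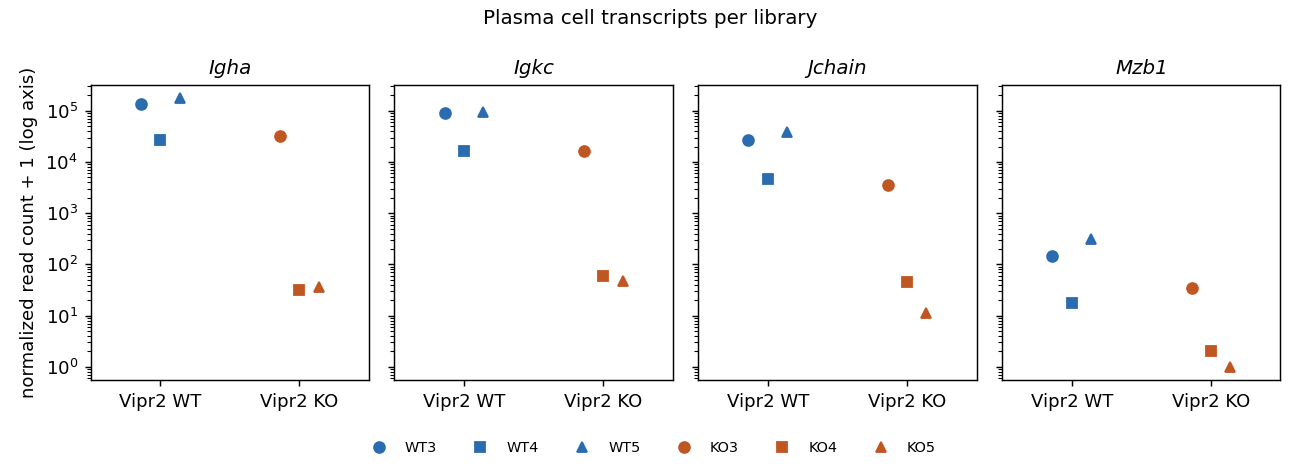
Normalized read count plus 1 (vertical axis, log scale) of the plasma cell transcripts Igha, Igkc, Jchain and Mzb1 in each wild-type (blue) and knockout (orange) library. Symbols mark the column number. Knockout libraries 4 and 5 lie far below the other 4 libraries in Igha, Igkc and Jchain.

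Markers of the other cell types did not pass as lists in the unpaired camera test. NCR+ ILC3 markers (10 of 12 lower, adjusted p = 0.074) included Il12rb2, at 195.7 ± 15.1 (SD, n = 3) in wild type and 38.5 ± 28.1 (n = 3) in knockout, and Klrd1 at 38.4 and 12.7. Their most abundant members Il2rb (96460 and 99820), Cxcr6 (73820 and 69160) and Klrb1b (27280 and 26740) missed the test. With the column number as a replicate block the NCR+ list's camera adjusted p was 0.0154, but 0.426 with an estimated correlation. NK cell and ILC1 markers (10 of 13 lower, adjusted p = 0.240) were led in level by Klrk1 (4125 in wild type, 4010 in knockout), Gzmb (2548 and 2204) and Ncr1 (1396 and 1009). Nkg7 and Klrc1 had their smallest p (log2 fold changes −0.50 and 0.99). ILC2 markers (7 of 14 higher, adjusted p = 0.909) were led by Cd81 (11870 and 14180), Gata3 (7002 and 6678) and Areg (4441 and 4027), with the sparse Il1rl1 at 22.1 and 69.5. T cell markers (9 of 15 higher, adjusted p = 0.536) were led by Tcrg-C1 (5439 and 4800), Trbc1 (1107 and 1129) and Trbc2 (1059 and 1136). Themis (7.67 and 35.8) and Cd40lg (150.9 and 217.8) had their smallest p.

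Myeloid markers (5 of 13 higher, adjusted p = 0.536) were led by Fcer1g (16650 in wild type and 16450 in knockout), Zbtb46 (9002 and 9150) and Xcr1 (1006 and 1050), with Adgre1 at 155.6 and 391.5 and Flt3 at 157.6 and 75.5. Epithelial markers (12 of 14 lower, adjusted p = 0.0577) were led by Lgals4 (221.5 and 229.5), Defa24 (196.4 and 6.85) and Fabp2 (158.4 and 3.53). Most Defa24 and Fabp2 reads came from wild-type library 5, with 577.6 and 467.7. Muc2 (32.0 and 0.632) and Lyz1 (54.7 and 2.00) had the smallest p of this list. Among mast cell and granulocyte markers (4 tested, adjusted p = 0.909) Cpa3 (89.8 and 40.7), Siglecf (4.38 and 44.8) and Prg2 (26.0 and 3.48) were highest, and Siglecf rose adjusted over the list alone (limma adjusted p = 0.0387). Stromal, endothelial and glial markers (5 tested, adjusted p = 0.242) were Pecam1 (4024 and 4186), Tagln (44.6 and 75.4), Lum (18.6 and 78.3) and less abundant genes. No erythroid or platelet marker reached the filter, and the highest were Itga2b (13.0 and 5.35), Pf4 (12.6 and 2.62) and Hba-a1 (6.88 and 3.75).

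The design ties genotype to 2 stretches of DNA, around Ptprc, where the donors carry different CD45 alleles, and around Vipr2. The 198 tested genes within 20 Mb of Ptprc did not shift in 1 direction (camera adjusted p = 0.716; 90 higher, 108 lower), nor did the 152 near Vipr2 (adjusted p = 0.716). Both sets passed fry in either direction (fry mixed adjusted p = 2.26e-05 near Ptprc and 2.96e-05 near Vipr2). That test asks whether a set holds any change and does not compare it with genes elsewhere. Without called genes, Vipr2 among them, and 20 immunoglobulin genes near Vipr2 the adjusted p was 0.00133 near Ptprc and 5.11e-05 near Vipr2. Among uncalled genes the odds ratio of an unadjusted p under 0.05 against genes elsewhere was 2.89 (95% interval 1.82 to 4.42) near Ptprc and 2.05 (1.11 to 3.52) near Vipr2, the latter 1.71 (0.829 to 3.2) without immunoglobulin genes. All 3 genes that limma called besides Vipr2 lay within 20 Mb of Ptprc, a window with 1.45% of the tested genes. Ptprc RNA itself was at 12100 ± 120 (SD, n = 3) in wild type and 12270 ± 344 (n = 3) in knockout. Esyt2 and Zfp386, which flank Vipr2 and were singled out after their values were seen, were lower in knockout by log2 fold changes of −0.75 ± 0.19 and −0.75 ± 0.20 (SE; limma adjusted p = 0.939 for each).

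**Figure D4:**
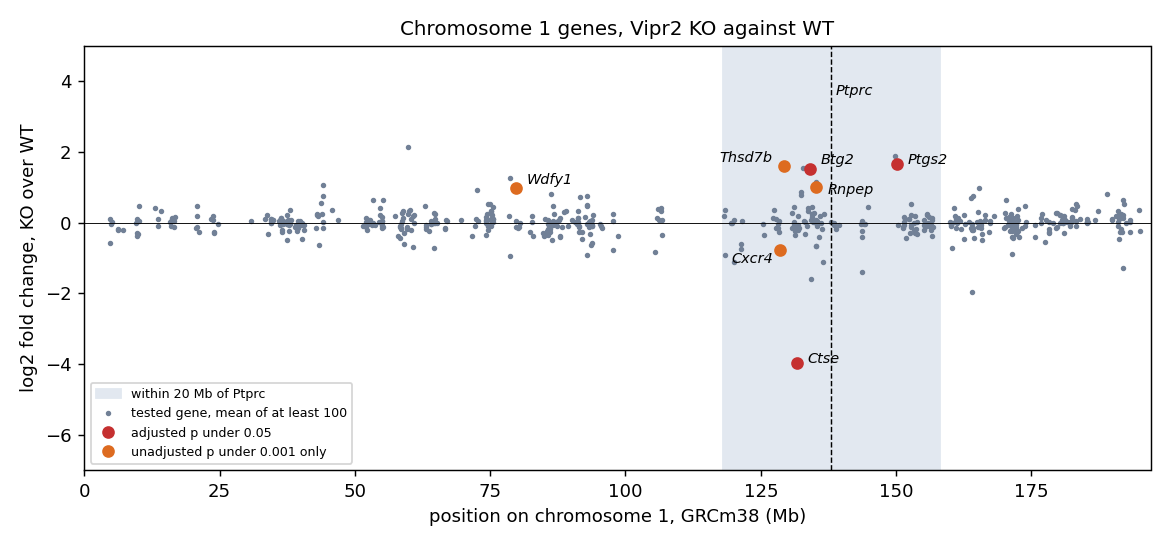
Log2 fold change, knockout over wild type (vertical axis), of tested chromosome 1 genes with a mean of at least 100 by position (horizontal axis, Mb, GRCm38). Shading marks 20 Mb on either side of Ptprc (dashed line), red points genes with an adjusted p under 0.05 and orange points named genes with an unadjusted p under 0.001. Ctse, Btg2 and Ptgs2 all lie in the shaded window.

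By principal components the first axis held 30.5% of the variance and set wild-type library 5 (score 124.9) apart from the other 5 (−33.6 to −16.8). The second axis, with 20.7%, placed the wild-type libraries between 6.7 and 77.3 and the knockout libraries between −73.4 and −9.6. Correlations of log2 values were 0.884 to 0.916 within wild type, 0.926 to 0.940 within knockout and 0.890 to 0.932 between genotypes.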

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

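Some alternatives were chosen after seeing the data. They left out genes near Ptprc, Vipr2 or the immediate early members of the cAMP list. Others used fry in either direction, or fry or estimated correlations with the replicate block. Grouping by description had been the planned main grouping and was run as an added alternative, alone or with a block by described mouse. The 4 called genes were the same under the other pseudocounts, filters, scalings and weights, robust eBayes, edgeR and genotype from the titles, which is the grouping used. DESeq2 called 65 genes and 10 lists, and these 65 included the 4. Leaving out libraries gave 0 to 6 genes, 3 to 8 lists and a Vipr2 log2 fold change of −8.44 to −7.81, with fewer libraries to estimate spread. Among these Vipr2 missed the threshold only without both number 3 libraries (adjusted p = 0.161). Btg2 also missed it without knockout library 4 (adjusted p 0.052; its range over libraries left out was 0.00333 to 0.38). The immediate early list reversed without knockout library 5 (adjusted p = 0.867, against 1.5e-08 to 0.417 when other libraries were left out). Estimated correlations called 0 lists, and fry 1 list by direction and 1 in either direction, both the receptor list. Fry in either direction called both loci (2), with and without called and immunoglobulin genes, and with the replicate block. Without genes near Ptprc 1 gene was left, Vipr2, by construction. The setting with genotype from the descriptions called 0 genes (478 at an unadjusted p under 0.05) and 0 lists, with Vipr2 at −2.52. Its replicate block by described mouse gave 0 genes, 1 list and −2.52. Here 1 library with Vipr2 reads and 1 nearly without change places.

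No label ties a column number to a mouse, and correlations at the fixed filter did not settle whether equal numbers are pairs. Deviations from the group means correlated at 0.05, 0.02 and 0.07 for numbers 3, 4 and 5, and 5 of 6 libraries correlated best with their own number. In checks chosen afterwards the values were 0.17, 0.10 and 0.13 among genes with a mean of at least 100. From 1000 on they were 0.33, 0.21 and 0.20. In both checks 6 of 6 libraries correlated best with their own number. Between unlike numbers the highest correlation was 0.03 at the fixed filter, −0.03 from 100 on and 0 from 1000 on. These later checks favour pairs by number, without proving them. With the number as a replicate block limma called the same 4 genes and 8 lists, and Vipr2 stayed at −8.16. Adjusted p was 0.0123 for the NF-κB, 0.022 for the STAT3 and IL-23 and 0.0154 for the NCR+ ILC3 list, 1.5e-11 for the immediate early list, and 0.0784 for the receptor list, not called. With estimated correlations under the block 0 lists were called (0.426 or more). Fry with the block called 2 lists by direction, immediate early and receptor (both 0.0485). In either direction it called 8: immediate early and T cell (both 0.00161), ILC3 cytokine and receptor (both 0.0087), migration (0.0236), cAMP and CREB (0.0369), and STAT3 and mast cell lists (both 0.0371). Of 26 immediate early genes 14 were higher in knockout at every number and 0 lower. The replicate block gave 4 genes in edgeR and 100 genes and 12 lists in DESeq2. Causes of these differences were not tested. At 31395314 reads or more, depth limits sparse transcripts. The 3 libraries per group limit smaller changes.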

Other observations

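The tests of position, of read loss, of immunoglobulin ratios, of genotype for Igha, of handling and of lists over the splits were chosen only after the results they bear on were seen. Those of genotype for Igha and of handling replaced earlier versions, which had been labelled as excluding both accounts.

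Among 13 genes other than Vipr2 with a mean of at least 100 and an unadjusted limma p under 0.001, 7 lay within 20 Mb of Ptprc: Ctse, Btg2, Ptgs2, Cxcr4, Thsd7b, Rnpep and Gm26642. In windows of 10 Mb across the genome, the one from 130 to 140 Mb on chromosome 1 held 53 such expressed genes, of which 14 had a p under 0.05. Its mean absolute z of 1.28 ranked 1. The nonclassical MHC genes H2-Q6 and H2-Q7, close paralogs that can share reads, were also higher in knockout, with log2 fold changes of 0.41 ± 0.076 and 0.35 ± 0.066 (SE) and adjusted p = 0.529. All 13 genes in this paragraph were chosen by their values, and 3 of them passed the adjusted threshold.

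The 3 genes called besides Vipr2 in limma and in edgeR all lie near Ptprc, against 7 of 65 genes in DESeq2. If loss of Vipr2 had changed genes irrespective of position, 3 of 3 would fall there with a hypergeometric p of 3e-06, which argues against that account of these 3 genes but says nothing of the DESeq2 calls elsewhere. Passenger DNA of the CD45.1 donor is a candidate explanation: among genes not called, 26 of 195 in the window had an unadjusted p under 0.05 against 676 of 13383 elsewhere, an odds ratio of 2.89 (95% interval 1.82 to 4.42, Fisher's exact test over genes, which are not independent). Loss of reads from non-reference alleles of the wild-type donor would lower wild type, which the Ctse log2 fold change of −3.96 excludes for that gene. For Btg2 and Ptgs2 (smaller log2 fold change 1.52) it stays open, as gene totals hold no allele counts. An effect of Vipr2 loss on any single gene of the window also stays open, since every knockout library differs from wild type at both loci.

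Plasma cell transcripts varied far more than the ILC3 genes. A small number of plasma cells or their RNA in the sorted fraction is a candidate source. The SD of log2(Igkc/Igha) over the 6 libraries was 0.134 of the SD of log2(Igha), so both transcripts went up and down together. Igkc/Igha was 0.671, 0.62, 0.539 and 0.517 in wild-type libraries 3, 4 and 5 and knockout library 3, but 1.9 and 1.33 in knockout libraries 4 and 5, where Igha had 31 and 33 reads. The gate removed CD19-positive cells and required Thy1.2 and CCR6, which would be expected to remove most plasma cells, and CD138 is not among the antibodies listed. Of 11 other plasma cell genes tested 7 were lower in knockout (median log2 fold change −0.45), but Sdc1 and Edem1 were abundant in all libraries. Genotype of the sorted cells stays open: the exact permutation p was 0.2, and 3 against 3 libraries cannot go below 0.1, so this test could not decide.

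The immediate early list was higher in knockout with Btg2 as its only called member. The list's call was lost with an estimated correlation (adjusted p = 0.667). Its sign reversed without knockout library 5 (adjusted p = 0.867), which leaves wild-type library 5 unmatched. The call was kept without both libraries numbered 5 (adjusted p = 7.61e-07). With the column number as a replicate block the adjusted p was 1.5e-11 in camera and 0.0485 in fry, but 0.426 with an estimated correlation. At every number 14 of 26 members were higher in knockout and 0 lower. Without genes near Ptprc, among them its members Btg2 and Ier5, the list's unpaired camera adjusted p was 0.101. Its mean log2 fold change was 0.13 in place of 0.181, with a median of 0.096 both before and after. That setting also took the window's other genes out of the background, and Btg2, at 1.52, was not left out alone. The lost call can therefore not be credited to Btg2 by test, although Ier5, the other member left out, was at 0.064. The 24 genes left lie outside the window, and 21 of them were above 0. With the median unchanged, this argues against genes near Ptprc accounting for the small shift of these 24 genes. Whether the list's call rested on Btg2 stays open. The design text says that both genotypes came from the same mice, so they shared the digestion up to the sort by CD45 allotype. A harsher digestion of the knockout cells is at odds with that design. Harsher handling from the sort on cannot be told apart. Across the list's 24 genes outside the window the excess in the number 5 libraries and the knockout change had a Spearman rho of 0.23 (permutation p = 0.28), and genes are not independent replicates. Lower cAMP signalling in cells without a Gs-coupled receptor was not tested as a cause. It would be expected to lower genes downstream of cAMP. The cAMP and CREB response list went slightly up in knockout, with 16 of 24 genes higher (camera adjusted p = 0.0307, 0.366 with an estimated correlation). Its mean log2 fold change was −0.005. Its members Fos, Fosb, Dusp1 and Atf3 also belong to the immediate early list, so the list is not a readout of cAMP alone. Its direction therefore cannot decide whether cAMP signalling was lower.

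Among the 10 splits of the 6 libraries into 3 and 3, 1 gave as many as 4 genes, the real one, and the highest other gave 0. The real split called 6 lists and the highest other 5. Genes with an unadjusted p under 0.05 numbered 742 in the real split, and 4 others gave more, up to 968. With 10 splits the share cannot fall under 0.05.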
